A study of Homo sapiens with 16 samples.

How the data were processed

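Messenger RNA was measured in OV90, an established ovarian serous carcinoma cell line, carrying an shRNA against RelA or against RelB and grown attached or as spheroids. Per the labels, attached cells were kept in RPMI 1640 with 10% tetracycline-free fetal calf serum, and spheroids in ultra-low attachment plates in DMEM-F12 with 1% KnockOut serum replacement, EGF at 20 ng/mL and FGF at 10 ng/mL. Growth lasted 6 days with medium supplemented at 72 h, RNA was taken with RNeasy, and libraries were made with TruSeq Stranded mRNA, per the labels' protocols. The 16 libraries form 4 groups of 4, and every library was used. The growth conditions differ in medium, serum and growth factors as well as attachment, so these act together in each comparison of growth.

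The authors deposited RSEM expected counts for each library, which are not normalised, after adapter trimming with cutadapt and alignment with STAR, per the submitters' processing notes, which name builds hg38 and GRCh38 and give no tool versions. The same per-library tables hold TPM, which sum to 1e6 over all genes of the table, per the file headers. The authors also deposited a series-wide table whose values are a signal on the CPM scale with TMM factors, per its name. There 100% of the values of each library were whole multiples of the signal of 1 read, within 0.1 read, so whole reads could be recovered. Its 31247 genes follow another annotation than the 56632 genes of the per-library tables, and 27878 genes are in both. Its 26 copies of pseudoautosomal genes on Y were left out. Of the deposited expected counts, 9.2% were not whole numbers.

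Gene identifiers were used as deposited. A table of gene names paired 49995 of the 56632 identifiers with a symbol, GENCODE release 29 held 50276 of them, and 6356 were in neither. Coordinates are those of GENCODE release 29 on GRCh38, which may be another release than the one used for alignment. Totals ran from 9739838 to 16531644 expected counts per library. Intervals and floors given for single genes cover counting error only.

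Expected counts were rounded and filtered with filterByExpr (minimum count 10, minimum total 15), which left 14412 genes. TMM factors were then applied, and 1 edgeR 4.0.16 quasi-likelihood fit with robust estimation covered the 4 groups and all 16 libraries, in R 4.3.3. The 5 contrasts were spheroid against adherent growth in each line, shRelB against shRelA in each growth condition, and the difference between the lines in the spheroid effect. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 14412 genes. The error given with a log2 change is its standard error, taken as the size of the change over the square root of the test's F value. Levels are CPM on TMM-scaled totals, given as mean and SD of 4 libraries. RELA and RELB were also compared by an exact two-sided permutation test of mean log2(CPM + 0.5) over the 70 assignments of 8 libraries to the lines, whose smallest possible p is 0.029.

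Gene lists were fixed from textbook knowledge before the data were examined, as were the contrasts, the main test, the rule for named genes and the alternatives, apart from those marked below. The 39 lists covered NF-kB canonical targets, the non-canonical NF-kB pathway, integrin subunits, integrin ligands and matrix, focal adhesion, hypoxia, glycolysis, cholesterol and fatty acid synthesis, the unfolded protein response, ATF4 targets, DNA replication, mitosis, EMT, epithelial junctions, stem-like markers, type I interferon, antigen presentation, NRF2 targets, p53 targets, apoptosis, homologous recombination, drug transporters, ribosome biogenesis, ribosomal proteins, nuclear and mitochondrial genes of the respiratory chain, YAP and TAZ targets, SRF and actin, TGF-beta targets, WNT targets, immediate early genes, heat shock, lysosome and autophagy, metallothioneins, Mullerian markers, and markers of leukocytes, fibroblasts and endothelium. Each was tested with limma 3.58.1 camera on voom values at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. A list needed 5 tested members, and 9 symbols found no identifier. Members were counted past the edgeR threshold over all genes, and again with p adjusted over the list alone.

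Named genes follow a fixed rule. In each comparison the first part takes the 8 called protein-coding genes with the largest log2 change each way (6 for the difference between lines), with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, which was not asked for the difference. The second part takes the 4 members with the smallest adjusted p from each called list, and 2 from any other list with at least 3 called members. RELA, RELB, REL, NFKB1, NFKB2 and every called integrin subunit complete it. Names beyond the first part could be left out in order of adjusted p. Some genes that the rule names are not reported here. Where a group had 0 counts the fold is a bound against a floor of 3 counts over its 4 libraries, and with 1 to 3 counts a ratio with its 95% counting interval.

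Runs of neighbouring genes were sought after the data were seen, as medians of log2 changes over windows of 25 genes in genome order, moved by 5 genes, among genes with a mean log2 CPM over 2. The threshold was the 95% point of the largest absolute median over 100 shuffles of the gene order. A list of liver-secreted proteins was also written after the data were seen.

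The edgeR and camera steps were tested on simulated data, with 50 genes planted at each of 4 folds and a list of targets shifted by 0.7 on the log2 scale. For the difference between lines, 36% of genes planted at 1.5-fold, 64% at 2-fold, 86% at 4-fold and 94% at 8-fold were found, with 9 of 13920 unchanged genes called. For spheroid against adherent growth in shRelB these shares were 56%, 78%, 96% and 96%, with 16 unchanged genes called. For shRelB against shRelA in spheroids they were 52%, 86%, 100% and 98%, with 7 unchanged genes called. The shifted list was called in the contrasts it was shifted in, and 0 of the 38 other lists were. Genes were simulated independently of each other, so this does not show how the list test behaves with correlated genes. All groups were simulated with the same spread for a gene, and few genes were changed. The shares found therefore do not show how the fit behaves with unequal spread or with many changed genes. Other splits of the real libraries, given further on, did call lists. The search for runs found 0 of 16 planted windows in its first simulated setting, where the shift of 0.6 lay close to the threshold. A wider set of settings was then run, and with shuffled real fold changes it found 1.2% of planted windows at a shift of 0.3, 67.5% at 0.5 and 98.1% at 0.6, and with Gaussian noise 0% at 0.3, 8.8% at 0.5, 23.1% at 0.6 and 76.9% at 0.8. At each of these shifts it found 0 of 16960 other windows. Smaller shifts would thus be missed.

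Alternatives were RLE size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom on rounded and unrounded counts, no filter and a filter of 1 CPM in 8 libraries. Others were a fit of the compared groups alone, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. RELA and RELB also had the deposited TPM and a pseudocount of 1, and lists had an estimated correlation. Reads recovered from the series-wide table and a fit without genes of the runs were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.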

Results

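Messenger RNA was sequenced from 16 libraries of OV90 cells, 4 each of shRelA adherent, shRelB adherent, shRelA spheroid and shRelB spheroid, taken after 6 days of growth. RelA and RelB are subunits of the NF-kB transcription factors. The study asks about RelB and integrins in how tumour cells of serous ovarian carcinoma withstand stress and return after treatment. Total expected counts of replicates 1 to 4 were 15312529, 11632706, 14890577 and 13421578 in shRelA adherent cells and 16531644, 12724689, 13242647 and 14277304 in shRelB adherent cells. The spheroid totals were 11704066, 11953392, 10904374 and 11474509 in shRelA and 12380761, 9739838, 11974931 and 11072855 in shRelB. The 4 groups lay apart on the first principal components, which held 42.5% and 30.6% of the variance. The spread between replicates was wider in shRelA than in shRelB cells, with a biological coefficient of variation of 0.126 and 0.107 in adherent and spheroid shRelA cells against 0.053 and 0.069 in shRelB. The main fit shared 1 spread per gene over the groups, so shares of genes called in the lines are not strictly comparable. For spheroid growth in shRelA, fitting the compared groups alone gave 3319 genes higher and 3227 lower, against 3983 and 3727 in the main fit. In shRelB it gave 4430 and 4361, against 4130 and 4012. No library carried a control shRNA, so a difference between the lines cannot be assigned to either knockdown. The labels do not say whether replicates were separate cultures, so p-values may measure technical spread only.

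RELA (ENSG00000173039, chromosome 11, 65653596 to 65663094) stood lower in shRelA cells in both growth conditions. Its level was 16.8 ± 1.19 CPM (SD, n = 4) in adherent shRelA cells and 51.7 ± 3.15 in adherent shRelB cells, or 32.6% of the other line. In spheroids it was 23.4 ± 2.06 and 50.9 ± 1.76 CPM, or 46.0%. RELB (ENSG00000104856, chromosome 19, 45001430 to 45038198) was lower in spheroids of the libraries labelled shRelB, at 7.44 ± 1.17 against 12.9 ± 1.98 CPM, or 57.6%. In adherent growth RELB was 10.5 ± 2.16 CPM in the libraries labelled shRelB and 9.12 ± 1.35 in shRelA, so it was not lower there. The exact two-sided permutation p was 0.029, the smallest possible, for RELA in both growth conditions and for RELB in spheroids, and 0.31 for RELB in adherent cells. Directions given below for shRelB against shRelA in adherent cells thus compare libraries whose RELB levels did not separate. The labels name tetracycline-free serum for adherent cells and do not say whether the shRNA needs induction.

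**Figure D1:**
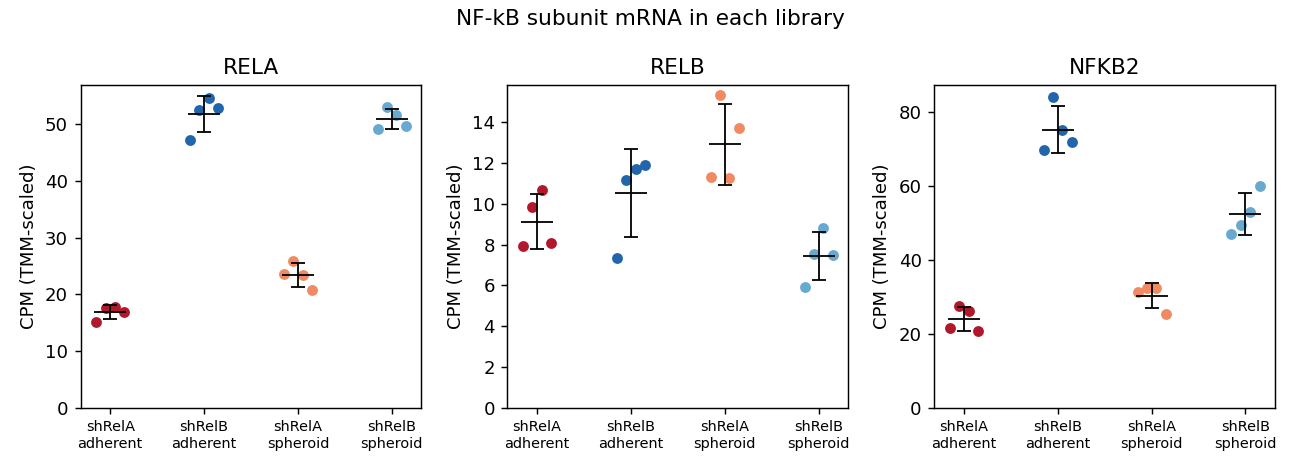
Levels of RELA, RELB and NFKB2 in CPM on the y axis for each library of the 4 groups on the x axis, with each group's mean as a line and bars of 1 SD. RELA was lower in all 8 shRelA libraries than in any shRelB library, and RELB was lower in the libraries labelled shRelB in spheroids alone.

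The question of the first comparison was how shRelA cells differ between spheroid and adherent growth. Genes of DNA replication were lower in spheroids (adjusted p = 0.095 for the list with an estimated correlation), with TYMS, the thymidylate synthase, at -1.22 ± 0.06 on the log2 scale, the replication clamp PCNA at -1.05 ± 0.06 and the ribonucleotide reductase subunit RRM2 at -1.27 ± 0.08 (n = 4 per group). Among canonical NF-kB targets (adjusted p = 0.19 for the list with an estimated correlation), the chemokine CXCL2 rose from 2.50 ± 0.835 to 21.5 ± 2.91 CPM (3.08 ± 0.16) and the adhesion molecule ICAM1 rose from 9.81 ± 1.23 to 24.4 ± 3.05 CPM (1.31 ± 0.11). Interferon-inducible OAS1 (2.51 ± 0.11) and IFI6 (3.35 ± 0.16) rose as well, and the YAP target AMOTL2 fell from 72.3 ± 10.9 to 19.3 ± 2.19 CPM (-1.91 ± 0.10). In edgeR 3983 genes were higher and 3727 lower of 14412 tested, or 53.5% of them.

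Of the genes with the largest changes in shRelA cells, PIGR, the polymeric immunoglobulin receptor (ENSG00000162896, chromosome 1, 206928518 to 206946466), rose from 0.0845 ± 0.0818 to 12.8 ± 1.72 CPM (7.01 ± 0.32, adjusted p = 2e-14). IGFBP5, an IGF-binding protein (ENSG00000115461, chromosome 2, 216672105 to 216695525), rose from 0.835 ± 0.465 to 68.1 ± 13.4 CPM (6.37 ± 0.25, adjusted p = 8.1e-12). ABCA10 (5.99), FEZ1 (4.56), ANKRD22 (4.47), CA4 (4.47) and MEP1A (4.29) were among those that followed. The largest falls were in TAGLN, an actin-binding protein, from 48.5 ± 23.6 to 3.45 ± 1.23 CPM (-3.80 ± 0.40, adjusted p = 3.3e-06), CPA4 (-3.72), AQP4 (-3.49), CHST9 (-3.30), TFEC (-3.24), NR1H4 (-2.84), TNFRSF19 (-2.72 ± 0.10) and the apolipoprotein gene APOB (-2.72 ± 0.17).

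Among the subunits in shRelA cells, RELA rose by 0.47 ± 0.08 (adjusted p = 4.7e-05), RELB by 0.50 ± 0.16 (0.009) and NFKB2 by 0.34 ± 0.10 (0.008), and REL fell by 0.89 ± 0.27 on the log2 scale (0.0082). NFKB1 was at -0.18 ± 0.09 (0.12). Of 37 tested NF-kB targets 23 rose and 3 fell, and 24 and 3 did so adjusted over the list alone, with a median of 0.71 (camera adjusted p = 8.66e-05, or adjusted p = 0.19 with an estimated correlation). PTGS2, the inducible cyclooxygenase (1.91 ± 0.14), and BCL3 (1.12 ± 0.10) were among them. Of 18 integrin subunits 7 rose and 3 fell, the same counts adjusted over the list alone, and the list was not called (0.433). The risers were ITGA10 (1.93 ± 0.31), ITGB6 (1.31 ± 0.20), ITGA7 (1.15 ± 0.25), ITGB3 (0.96 ± 0.35), ITGB5 (0.90 ± 0.08), ITGA6 (0.72 ± 0.13) and ITGA5 (0.63 ± 0.11), and ITGB8 (-0.80 ± 0.12), ITGAV (-0.74 ± 0.11) and ITGA3 (-0.62 ± 0.10) fell. ITGB3 was not called with reads of the series-wide table (0.93, adjusted p = 0.11), nor without shRelA adherent replicate 1 (adjusted p = 0.063) or 4 (0.075) or shRelA spheroid replicate 1 (0.08) or 3 (0.066). The test of NFKB1, spheroid against adherent in shRelA, passed without shRelA spheroid replicate 2 (-0.25, adjusted p = 0.033).

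Proliferation lists were lower in shRelA spheroids. DNA replication genes fell in 33 of 34 and rose in 0, the same over the list alone (median -0.75, adjusted p = 5.32e-17, or adjusted p = 0.095 with an estimated correlation). Mitosis genes fell in 28 of 34 and rose in 0, or 29 and 1 adjusted over the list alone (median -0.77, adjusted p = 2.66e-09, or 0.45 estimated). KIF23 stood at -1.08 ± 0.08 and CCNA2 at -1.32 ± 0.10. Homologous recombination genes fell in 23 of 29 and rose in 0, the same over the list alone (4.82e-08, or 0.13 estimated). FANCA stood at -0.98 ± 0.08 and BRCA1 at -0.79 ± 0.07. Cholesterol synthesis genes fell in 22 of 25 and rose in 1, the same over the list alone (median -0.69, 5.83e-09, or 0.23 estimated). MSMO1 stood at -1.27 ± 0.09 and IDI1 at -1.19 ± 0.09. Fatty acid genes fell in 8 of 14 and rose in 1 (0.0177, or 0.35 estimated), and the desaturase SCD stood at -1.18 ± 0.10. Further lists fell too, with 19 of 25 YAP and TAZ targets down and 3 up (2.91e-05, or 0.19 estimated). SRF and actin genes were down in 12 of 22 and up in 1, CALD1 at -1.26 ± 0.07 (0.000542, or 0.45 estimated). Focal adhesion genes were down in 13 of 26 and up in 4, TNS1 at -1.55 ± 0.09 (0.0227, or 0.48 estimated). Adjusted over the list alone the counts of those lists were the same, apart from 5 focal adhesion genes up. Without the genes of the chromosomal runs described further on, the focal adhesion call ended (adjusted p = 0.061).

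Immediate early genes rose in 25 of 30 and fell in 0 (median 0.77, adjusted p = 4.82e-08, or adjusted p = 0.13 with an estimated correlation). The phosphatase DUSP5 stood at 1.23 ± 0.07 and KLF2 at 1.72 ± 0.13. Lysosome and autophagy genes rose in 22 of 29 and fell in 1, or 23 and 1 adjusted over the list alone (median 0.60, 2.59e-07, or 0.13 estimated). GABARAPL1 stood at 1.96 ± 0.10 and the protease CTSD at 0.87 ± 0.06. Antigen presentation genes rose in 12 of 18, with HLA-DMB at 4.16 ± 0.21 and HLA-B at 1.27 ± 0.09 (0.000131, or 0.13 estimated), and interferon genes in 20 of 28 with 2 lower (0.000137, or 0.13 estimated). Nuclear respiratory chain genes rose in 28 of 34 and fell in 3 (median 0.33, 9.27e-06, or 0.45 estimated). The 5 metallothioneins tested rose, MT2A by 1.83 ± 0.23 (0.0123, or 0.32 estimated), and 9 of 17 drug transporter and detoxification genes rose with 1 lower, CYP1A1 by 4.15 ± 0.17 (0.0193, or 0.35 estimated). Apart from the lysosome counts and 2 lower drug transporter genes, these counts were the same adjusted over the list alone.

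Mitochondrially encoded genes rose in 5 of 13 and fell in 0 in shRelA spheroids, the same over the list alone (adjusted p = 0.0276, or adjusted p = 0.68 with an estimated correlation). MT-ND3 stood at 0.53 ± 0.09. Replicate 2 of shRelA adherent cells held 2.48% of its counts on the mitochondrial chromosome against 4.52% to 7.29% in the other libraries, and without it the call ended (adjusted p = 0.14), as it did without shRelA spheroid replicate 2 (0.065) or replicate 4 (0.057). Markers of other cell types moved with growth. LYZ rose from 231 ± 33.4 to 1060 ± 113 CPM and CD79A from 4.44 ± 1.17 to 38.1 ± 5.46, and 4 of 5 leukocyte markers rose with CSF1R lower (0.022, or 0.19 estimated). The endothelial markers TEK (3.20 ± 0.281 CPM in spheroids) and VWF (3.46 ± 0.417 CPM) rose with 1 further of 5 and 0 lower (0.0228, or 0.13 estimated), and 1 of 8 fibroblast markers rose with 3 lower (0.634). Both counts of leukocyte and endothelial markers were the same over the list alone.

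The other lists were not called in shRelA cells by camera. Their counts higher and lower were 12 and 7 of 27 integrin ligands and matrix genes (0.287), 10 and 6 of 25 hypoxia genes (0.107), 5 and 7 of 18 glycolysis genes (0.634), 8 and 8 of 21 unfolded protein response genes (0.941), and 6 and 6 of 24 ATF4 targets (0.975). They were 7 and 3 of 15 EMT genes (0.287), 9 and 9 of 28 epithelial genes (0.664), 8 and 6 of 16 stem-like markers (0.507), 8 and 5 of 23 NRF2 targets (0.438), 7 and 7 of 23 p53 targets (0.969), and 4 and 3 of 10 non-canonical NF-kB genes (0.941). Ribosome biogenesis genes stood at 5 and 12 of 29 (0.0804), ribosomal proteins at 4 and 4 of 36 (0.993), TGF-beta targets at 7 and 9 of 21 (0.664), WNT targets at 6 and 3 of 15 (0.882), heat shock proteins at 7 and 3 of 16 (0.307), Mullerian markers at 5 and 2 of 10 (0.664) and apoptosis regulators at 11 and 8 of 28 (0.496). Adjusted over the list alone these counts were the same, apart from 13 lower ribosome biogenesis genes, 3 and 3 ribosomal proteins and 12 higher apoptosis regulators. Median, mean and test had the same sign in every called list of all 5 comparisons, and differed in sign in uncalled ones here (glycolysis, ATF4, p53 and TGF-beta).

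The same question in shRelB cells gave lower replication and ribosome biogenesis genes in spheroids and higher lysosomal and antigen presentation genes, with adjusted p = 0.23 for each of these lists with an estimated correlation. TYMS stood at -1.02 ± 0.06, ODC1, the ornithine decarboxylase, at -1.23 ± 0.06 and the spermidine synthase SRM at -1.05 ± 0.08 on the log2 scale (n = 4 per group). AMOTL2 fell from 68.5 ± 2.15 to 15.6 ± 1.71 CPM (-2.13 ± 0.10), and CCN1, a secreted matrix protein and YAP target, from 196 ± 13.0 to 27.0 ± 1.05 CPM (-2.86 ± 0.25). HLA-B rose from 14.1 ± 1.91 to 52.6 ± 4.97 CPM (1.90 ± 0.10), and GABARAPL1 rose by 1.87 ± 0.10. In edgeR 4130 genes were higher and 4012 lower, or 56.5% of those tested.

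Among the largest rises in shRelB cells was that of UGT2B15, a glucuronosyltransferase (ENSG00000196620, chromosome 4, 68646630 to 68670628), from 0.592 ± 0.333 to 15.5 ± 1.80 CPM (4.69 ± 0.27, adjusted p = 1e-12). PIGR (4.51), FEZ1 (3.95), PDK4 (3.84), IGFBP5 (3.74), OLFM4 (3.61) and the steroid-metabolising enzyme AKR1C3 (3.37 ± 0.11) also rose. The largest falls were in TAGLN (-3.35 ± 0.36), PLXNC1 (-3.24 ± 0.15), SERPIND1, the thrombin inhibitor heparin cofactor II (-3.07 ± 0.19), SERPINB2 (-3.04 ± 0.62), CHST9 (-2.98), ANKRD1 (-2.95 ± 0.25), the fibrinogen gene FGA (-2.88 ± 0.27) and CCN1. SERPIND1 fell from 971 ± 32.3 to 116 ± 25.2 CPM (adjusted p = 8.2e-09).

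NFKB1 fell by 0.57 ± 0.09 on the log2 scale in shRelB spheroids (adjusted p = 1.2e-05), NFKB2 by 0.52 ± 0.10 (6.1e-05) and RELB by 0.49 ± 0.16 (0.012). RELA stood at -0.02 ± 0.07 (0.8) and REL at -0.39 ± 0.25 (0.19). Without shRelB spheroid replicate 1 RELB was not called (-0.39, adjusted p = 0.058). The test of REL, spheroid against adherent in shRelB, passed without that library (-0.67, adjusted p = 0.034) and with reads of the series-wide table (-0.45, adjusted p = 0.019). Of 37 NF-kB targets 17 fell and 7 rose, the same adjusted over the list alone (median -0.25, camera adjusted p = 0.0322, or adjusted p = 0.45 with an estimated correlation). CXCL6 stood at -1.44 ± 0.10, NFKBIA, the NF-kB inhibitor, at -1.23 ± 0.11, CXCL5 at -0.73 ± 0.09 and CD83 at 2.00 ± 0.24. Of 18 integrin subunits 4 rose and 7 fell, the same over the list alone, and the list was not called (0.488). ITGA2B (2.44 ± 0.40), ITGA10 (2.05 ± 0.23), ITGB6 (1.25 ± 0.20) and ITGA7 (0.95 ± 0.27) rose, and ITGB7 (-1.08 ± 0.18), ITGB8 (-0.95 ± 0.12), ITGA2 (-0.90 ± 0.14), ITGA3 (-0.78 ± 0.10), ITGB4 (-0.42 ± 0.13), ITGAV (-0.33 ± 0.11) and ITGB5 (-0.23 ± 0.08) fell.

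Ribosome biogenesis genes fell in 26 of 29 and rose in 0 in shRelB spheroids (median -0.56, adjusted p = 2.6e-09, or adjusted p = 0.23 with an estimated correlation), and replication genes fell in 32 of 34 and rose in 0 (median -0.58, 8.2e-11, or 0.23 estimated). YAP and TAZ targets fell in 18 of 25 and rose in 3 (median -0.74, 3.81e-06, or 0.23 estimated), SRF and actin genes fell in 17 of 22 and rose in 2, with FLNA at -0.91 ± 0.10 (6.32e-06, or 0.26 estimated), and focal adhesion genes fell in 16 of 26 and rose in 3 (8.89e-05, or 0.23 estimated). Lysosome genes rose in 20 of 29 and fell in 3 (median 0.67, 8.71e-06, or 0.23 estimated). CTSB stood at 1.07 ± 0.06. Antigen presentation genes rose in 10 of 18 and fell in 2, with HLA-C at 1.13 ± 0.06 (0.00096, or 0.23 estimated), and interferon genes rose in 20 of 28 and fell in 4 (0.00149, or 0.23 estimated). IFI6 stood at 2.51 ± 0.14. Adjusted over the list alone these counts were the same, apart from 18 lower SRF and actin genes.

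The further called lists in shRelB cells were cholesterol synthesis (18 of 25 lower and 2 higher, 0.000606), fatty acid synthesis (8 of 14 lower and 4 higher, SCD at -1.87 ± 0.10, 0.0118), glycolysis (9 of 18 lower and 3 higher, HK2 at -1.29 ± 0.10, 0.0382), mitosis (17 of 34 lower and 1 higher, 0.000325) and homologous recombination (19 of 29 lower and 1 higher, 0.000219), with p from 0.23 to 0.57 for all 19 called lists with an estimated correlation. Those called higher were the nuclear respiratory chain (20 of 34 higher and 3 lower, 0.00101), immediate early genes (17 of 30 higher and 2 lower, DUSP6 at 1.60 ± 0.07, 0.00506), drug transporters (9 of 17 higher and 2 lower, 0.0125), the 5 metallothioneins (0.007) and leukocyte markers (4 of 5 higher and 1 lower, 0.00793). Adjusted over the list alone these counts were the same, apart from 3 higher cholesterol genes, 20 lower recombination genes and 18 higher immediate early genes. LYZ rose from 112 ± 13.9 to 307 ± 30.1 CPM. Endothelial markers (3 of 5 higher and 0 lower, median 1.40, 0.0621) and fibroblast markers (1 of 8 higher and 3 lower, 0.504) were not called as lists, with the same counts over the list alone. The glycolysis call ended under the stricter filter (adjusted p = 0.056), without shRelB adherent replicate 4 (0.05) and without shRelB spheroid replicate 1 (0.055).

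Across genes, the spheroid effects of the lines ran together. Of 5665 genes called in both, 2777 were higher and 2662 lower in both (1141 and 1038 if independent), and 226 moved in opposite directions. Each of these 226 had a called difference, which nearly follows from opposite calls in the same fit. Pearson's r across 14412 genes, which are not independent replicates, was 0.694 and Spearman's correlation 0.711.

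The next comparison asked how shRelB and shRelA cells differ in adherent growth. NF-kB targets stood higher in the libraries labelled shRelB (adjusted p = 0.049 for the list with an estimated correlation), with the chemokine CXCL6 at 59.3 ± 2.39 against 10.4 ± 0.802 CPM (2.50 ± 0.10 on the log2 scale) and TNFAIP3, a feedback inhibitor of NF-kB, at 3.11 ± 0.19 (n = 4 per group). Matrix genes (adjusted p = 0.082 for the list with an estimated correlation) and mesenchymal genes (0.049) were higher as well, with SPP1, osteopontin, at 1380 ± 96.2 against 264 ± 11.9 CPM (2.39 ± 0.10), COL7A1 at 3.61 ± 0.21 and ZEB1 at 3.04 ± 0.19. Beside them, 5 of 8 fibroblast markers were higher and 2 lower (median 0.81, camera adjusted p = 0.14), and 3 of 5 endothelial markers were higher and 0 lower (median 2.15, 0.0791), with 2 and 2 of 5 leukocyte markers (0.821), the same counts over the list alone. Cholesterol synthesis genes were lower (adjusted p = 0.32 for the list with an estimated correlation), with INSIG1 at -1.61 ± 0.09 and MSMO1 at -1.38 ± 0.09. In edgeR 3637 genes were higher and 3682 lower, or 50.8% of those tested.

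CXCL5, a chemokine (ENSG00000163735, chromosome 4, 73995642 to 73998779), had 1 count over the 4 adherent shRelA libraries and 2359 over those labelled shRelB, a CPM ratio of 2340 with a 95% counting interval of 419 to 92300. CNTN1, a neural adhesion molecule (ENSG00000018236, chromosome 12, 40692442 to 41072418), was at 39.6 ± 4.76 against 0.278 ± 0.137 CPM (7.06 ± 0.21, adjusted p = 2e-18). LTB (5.89), UPK1B (5.69), IGFBP5 (5.31), P-selectin SELP (5.12 ± 0.13), TUSC3 (5.07) and CD3G (4.81) followed. DLC1 (ENSG00000164741, chromosome 8, 13083361 to 13604610), was at 14.8 ± 2.57 CPM in shRelA and 0 counts in shRelB, at least 276-fold lower. MYH4 (-7.51 ± 0.20), TFEC (-6.31), APOB (-4.88 ± 0.20), NWD2 (-4.79), SSTR1 (-4.67), the receptor NTRK2 (-4.63 ± 0.15) and DIP2C (-4.60) were next.

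NFKB2 was higher in the adherent libraries labelled shRelB by 1.65 ± 0.10 (adjusted p = 1.7e-12), RELA by 1.62 ± 0.08 (3.9e-14) and NFKB1 by 0.47 ± 0.09 (0.00012), and RELB (0.20 ± 0.16, 0.3) and REL (0.20 ± 0.24, 0.52) did not pass. Of 37 NF-kB targets 27 were higher and 1 lower, or 29 and 1 adjusted over the list alone (median 1.19, camera adjusted p = 3.03e-11, and 0.049 with an estimated correlation). EMT genes were higher in 11 of 15 and lower in 0, the same over the list alone (median 0.81, 3.02e-05, and 0.049 estimated). TGFBI stood at 2.57 ± 0.15 and SPARC at 1.45 ± 0.11. Of 18 integrin subunits 12 were higher and 2 lower, the same over the list alone (median 0.39, 0.00703, or 0.082 estimated). ITGA11 (2.18 ± 0.37), ITGA10 (1.64 ± 0.31), ITGA1 (1.43 ± 0.14), ITGA5 (1.02 ± 0.11), ITGB5 (0.88 ± 0.08), ITGB7 (0.72 ± 0.18), ITGA2 (0.58 ± 0.13), ITGA6 (0.46 ± 0.13), ITGB4 (0.42 ± 0.13), ITGB8 (0.35 ± 0.11), ITGAV (0.35 ± 0.11) and ITGB1 (0.31 ± 0.07) were higher, and ITGA2B (-1.11 ± 0.44) and ITGA3 (-0.26 ± 0.10) lower. ITGA2B was not called with reads of the series-wide table (-0.64, adjusted p = 0.25), by DESeq2 (0.065) or limma-voom (0.079), or without shRelA adherent replicate 1 (0.15) or 4 (0.078) or shRelB adherent replicate 1 (0.05), 2 (0.1), 3 (0.055) or 4 (0.064). ITGA3 was not called without shRelA adherent replicate 1 (adjusted p = 0.077) or 4 (-0.16, adjusted p = 0.14) or shRelB adherent replicate 3 (0.095), or in a fit of the compared groups alone (0.089).

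Integrin ligands and matrix genes were higher in 16 of 27 and lower in 3 (median 0.62, adjusted p = 0.000266, or adjusted p = 0.082 with an estimated correlation), and TGF-beta targets in 14 of 21 with 4 lower, LTBP2 at 2.32 ± 0.18 and ID2 at -1.14 ± 0.07 (0.00703, or 0.082 estimated). Heat shock proteins were higher in 12 of 16 and lower in 0, or 14 and 0 adjusted over the list alone (0.00037, or 0.082 estimated). HSPB8 stood at 3.64 ± 0.38. Ribosome biogenesis genes were higher in 20 of 29 and lower in 1, or 22 and 1 over the list alone (0.000279, or 0.51 estimated). NOP2 stood at 1.01 ± 0.08. Glycolysis genes were higher in 11 of 18 and lower in 3, or 12 and 3 over the list alone (0.00188, or 0.32 estimated). The lactate dehydrogenase LDHA stood at 1.40 ± 0.06. Cholesterol genes were lower in 21 of 25 and higher in 2 (median -0.79, 8.24e-08, or 0.32 estimated), and replication genes lower in 17 of 34 and higher in 1, PCNA at -0.83 ± 0.06 (0.00529, or 0.51 estimated). Focal adhesion (12 of 26 higher and 3 lower, CSRP1 at 4.79 ± 0.18, 0.0191) and immediate early genes (13 of 30 higher and 2 lower, IER5 at 1.05 ± 0.08, 0.0287) were called higher, and the unfolded protein response (12 of 21 lower and 3 higher, HYOU1 at -0.72 ± 0.05, 0.0322) and ATF4 targets (13 of 24 lower and 1 higher, 0.0287) lower, with p of 0.27 to 0.57 for these lists with an estimated correlation. Adjusted over the list alone the counts not given so far were the same, apart from 5 lower focal adhesion genes, 13 lower unfolded protein genes and 3 higher ATF4 targets. Calls ended for immediate early genes without shRelA adherent replicate 1 (adjusted p = 0.061) or replicate 4 (0.06), for ATF4 targets without shRelA adherent replicate 3 (0.07), and for the unfolded protein response without genes of the chromosomal runs (0.054).

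In spheroids, the comparison of shRelB with shRelA gave lower epithelial and cholesterol synthesis genes and higher heat shock genes. With an estimated correlation none of these 3 list calls stayed (adjusted p = 0.78, 0.78 and 0.73). P-cadherin CDH3 was at 0.577 ± 0.257 against 7.63 ± 1.45 CPM (-3.68 ± 0.30 on the log2 scale), the epithelial splicing factor ESRP1 at -0.94 ± 0.09 and DHCR7, an enzyme of cholesterol synthesis, at 60.9 ± 1.91 against 154 ± 17.3 CPM (-1.34 ± 0.09, n = 4 per group). HSPB1 was higher by 0.96 ± 0.10. ICAM1, higher in adherent cells labelled shRelB, was lower in their spheroids, at 10.5 ± 0.859 against 24.4 ± 3.05 CPM (-1.21 ± 0.11). In edgeR 3347 genes were higher and 3462 lower, or 47.2% of those tested.

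CNTN1 had the largest rise among the named genes in spheroids labelled shRelB, at 94.5 ± 7.10 against 0.971 ± 0.433 CPM (6.60 ± 0.17, adjusted p = 1e-19), followed by CXCL5 (5.63 ± 0.17), CACNA1E (4.84), OLFM4 (4.81), SELP (4.62 ± 0.11), PEAR1 (4.47), CSRP1 (4.33) and SLC26A9 (4.17). MYH4, a skeletal muscle myosin (ENSG00000264424, chromosome 17, 10443290 to 10469559), was at 42.6 ± 4.49 CPM in shRelA and 0 counts in shRelB, at least 649-fold lower. TDO2 (-5.74), NWD2 (-5.70), APOB (-5.55 ± 0.34), ITPRID1 (-5.52), A2M, the protease inhibitor alpha-2-macroglobulin (-5.43 ± 0.16), DIP2C (-5.04) and SSTR1 (-4.90) were next.

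RELB was lower in spheroids labelled shRelB by -0.80 ± 0.16 (adjusted p = 0.00026), and RELA (1.12 ± 0.08, 3.7e-11), NFKB2 (0.79 ± 0.10, 6.9e-07) and REL (0.69 ± 0.28, 0.045) were higher. NFKB1 stood at 0.08 ± 0.10 (0.55). NF-kB targets were higher in 21 of 37 and lower in 7, the same over the list alone, and the list was not called (median 0.43, camera adjusted p = 0.0537). Of 18 integrin subunits 6 were higher and 4 lower, the same over the list alone, without a call (0.487). ITGA11 (2.07 ± 0.41), ITGA10 (1.76 ± 0.23), ITGA1 (1.27 ± 0.14), ITGAV (0.76 ± 0.11), ITGA5 (0.38 ± 0.11) and ITGB1 (0.27 ± 0.07) were higher, and ITGB3 (-1.42 ± 0.38), ITGA7 (-0.65 ± 0.24), ITGA3 (-0.42 ± 0.10) and ITGB5 (-0.25 ± 0.08) lower. With reads of the series-wide table ITGB3 (-1.17, adjusted p = 0.064) and ITGA7 (-0.49, 0.082) were not called. ITGA7 was also lost by DESeq2 (adjusted p = 0.067) and without shRelA spheroid replicate 1 (-0.38, adjusted p = 0.21) or 3 (0.053) or shRelB spheroid replicate 1 (0.064), 2 (0.072) or 3 (0.065). REL was lost by DESeq2 (adjusted p = 0.067) and limma-voom (0.083), and without shRelA spheroid replicate 1 (0.08), 2 (0.51, adjusted p = 0.15) or 4 (0.053), shRelB spheroid replicate 1 (0.42, adjusted p = 0.25) or 2 (0.063), shRelA adherent replicate 4 (0.05) or shRelB adherent replicate 1 (0.055) or 3 (0.054).

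The 4 lists called in this comparison were cholesterol synthesis, lower in 14 of 25 and higher in 2, or 15 and 2 adjusted over the list alone (median -0.39, adjusted p = 0.00113, or adjusted p = 0.78 with an estimated correlation), epithelial junctions and keratins, lower in 17 of 28 and higher in 6, or 17 and 7 over the list alone (median -0.39, 0.0235, or 0.78 estimated), heat shock proteins, higher in 11 of 16 and lower in 0, the same over the list alone (median 0.23, 0.00483, or 0.73 estimated), and mitosis genes, higher in 14 of 34 and lower in 1, or 14 and 0 over the list alone, BUB1B at 0.77 ± 0.09 (median 0.26, 0.019, or 0.91 estimated). MYC was lower, at 44.7 ± 1.66 against 92.2 ± 5.8 CPM. Higher and lower counts, the same over the list alone, were 5 and 1 of 8 fibroblast markers (0.263), 2 and 0 of 5 endothelial markers (0.232) and 3 and 2 of 5 leukocyte markers (0.662), none of these lists being called by camera.

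Across genes the line differences of adherent and spheroid cells ran together. Of 4780 genes called in both, 2208 were higher and 2331 lower in both (845 and 884 if independent), and 241 moved in opposite directions. Each of these 241 had a called difference, which again nearly follows from the opposite calls. Pearson's r across genes was 0.736 and Spearman's correlation 0.659. Runs of neighbouring genes also differed between the lines in the same direction in both growth conditions. In each growth condition 147 of 2091 windows of 25 genes passed the threshold, 111 of them in both, against 2 windows in each spheroid effect. They formed 10 runs, the longest on chromosome 1, ending at 179229684, with a median of 0.57 in adherent cells and 0.60 in spheroids over 245 genes, and on chromosome 7 from 112206588 to 158830253, at -0.54 and -0.57 over 155 genes. Of the named genes with the largest changes, SELP and PEAR1 lie in runs on chromosome 1, and CPA4, TFEC and PDK4 in runs on chromosome 7. Of 1034 tested genes inside runs 74.2% were called in adherent cells and 74.7% in spheroids, against 49.0% and 45.1% outside, where 3244 were higher and 3308 lower in adherent cells and 2953 and 3084 in spheroids. The runs were chosen from these same changes, so their medians and the higher share called inside follow in part from that choice. Windows past the threshold in adherent cells held 1105 genes. In spheroids these had a median of 0.51 in the found direction, with 87.4% of genes in it. Windows past it in spheroids held 1145 genes, at 0.48 and 87.1% in adherent cells.

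**Figure D2:**
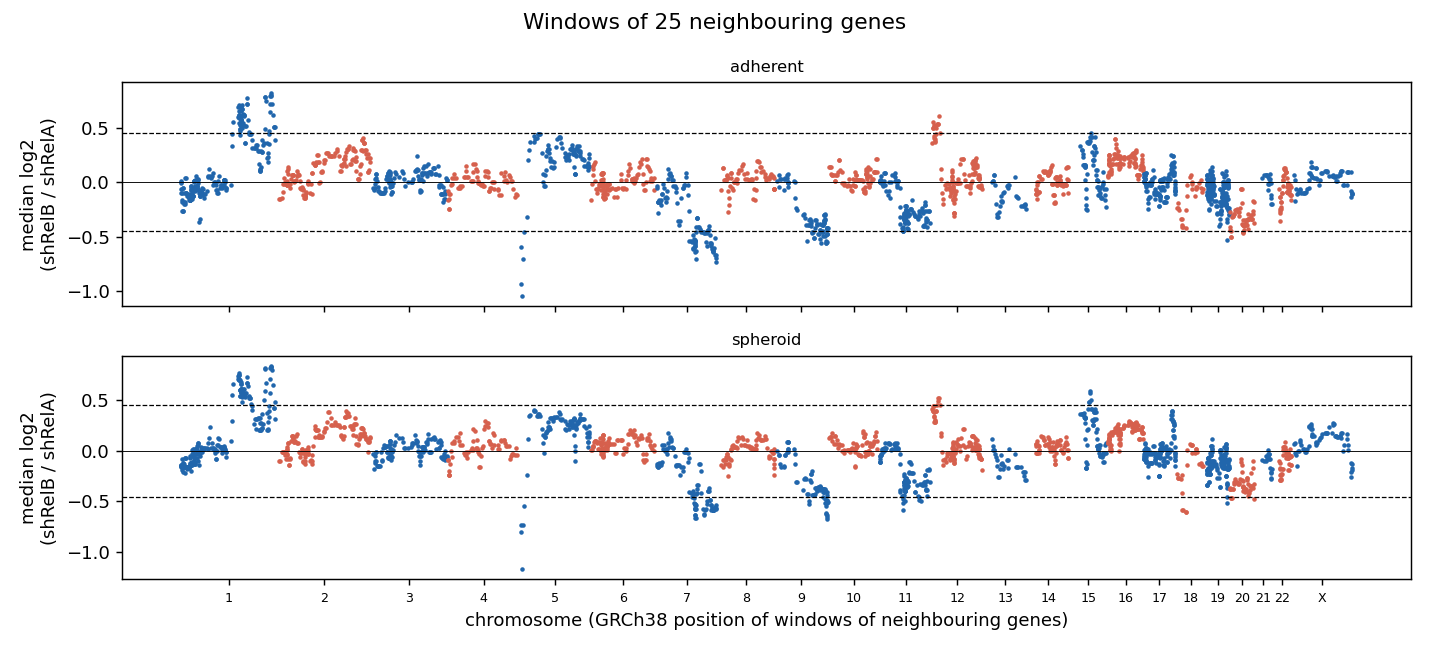
Each point is the median log2 ratio of shRelB to shRelA (y axis) over 25 neighbouring genes in genome order from chromosome 1 to X (x axis), in adherent cells above and spheroids below, with colours alternating by chromosome and dashed lines at the thresholds of 0.451 and 0.454. The long run on chromosome 1 lies above 0 and those on chromosome 7 below 0 in both panels.

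The last comparison asked whether the response to spheroid growth differs between the lines. As a list, canonical NF-kB targets had a lower spheroid effect in shRelB than in shRelA, a difference kept with an estimated correlation (adjusted p = 0.03). The opposite directions within the lines were not kept (0.19 in shRelA and 0.45 in shRelB). CXCL6 went from 10.4 ± 0.802 to 18.9 ± 3.32 CPM in shRelA and from 59.3 ± 2.39 to 21.9 ± 1.86 in shRelB (difference -2.29 ± 0.15 on the log2 scale, n = 4 per group), and BCL3 from 24.2 ± 3.17 to 52.5 ± 7.74 and from 50.4 ± 4.56 to 35.5 ± 2.89 CPM (-1.62 ± 0.15). Ribosome biogenesis genes were also lower in the difference, with MYC at -0.86 ± 0.15 (adjusted p = 0.25 for the list with an estimated correlation), and the integrin subunit ITGB5 rose from 105 ± 11.9 to 196 ± 18.9 CPM in shRelA and fell from 193 ± 9.57 to 165 ± 3.77 in shRelB (-1.13 ± 0.11). In edgeR 1108 genes had a higher and 1412 a lower spheroid effect in shRelB, or 17.5% of those tested.

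The largest positive differences were in TFEC (3.31 ± 1.0), PDK4, a kinase that restrains pyruvate oxidation (2.75 ± 0.53), the alcohol dehydrogenase ADH1C (2.15 ± 0.16, adjusted p = 1.4e-08), COL3A1 (2.11 ± 0.30), LRRC31 (1.64) and TENT5C (1.61). TFEC had 0.120 ± 0.0513 and 0.125 ± 0.195 CPM in shRelB, and its call ended without shRelB adherent replicate 2 (adjusted p = 0.05), shRelB adherent replicate 3 (0.052) or shRelB spheroid replicate 3 (1.49, adjusted p = 0.71). ADH1C went from 79.0 ± 9.16 to 70.4 ± 3.84 CPM in shRelA and from 23.6 ± 4.63 to 94.0 ± 9.85 in shRelB. CXCL5 and MYH4, which had 1 and 0 counts in a group, were called lower in the difference, with fitted values that depend on the prior count and are no bounds. BPIFB1 (-4.50 ± 0.51, adjusted p = 1.7e-06), TAAR1 (-3.89 ± 0.71), LTB (-3.88 ± 0.54) and IFI30 (-3.46 ± 0.47) followed, and with reads of the series-wide table IFI30 was not called (-0.55, adjusted p = 0.11).

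NFKB2 (-0.86 ± 0.14, adjusted p = 0.00015), RELB (-1.0 ± 0.23, 0.0033) and RELA (-0.50 ± 0.11, 0.0032) had a lower spheroid effect in shRelB. NFKB1 did too (-0.39 ± 0.13, 0.039), though not with reads of the series-wide table (-0.34, adjusted p = 0.079) or without shRelA adherent replicate 1 (0.08) or 4 (0.085), shRelB adherent replicate 2 (0.075) or 3 (0.089), shRelA spheroid replicate 2 (0.094) or 3 (0.056), or shRelB spheroid replicate 2 (0.083), 3 (0.092) or 4 (0.07). REL did not pass (0.49 ± 0.37, 0.4). Of 37 NF-kB targets 23 were lower in the difference and 0 higher, or 25 and 2 adjusted over the list alone (median -1.25, camera adjusted p = 1.68e-14, and 0.03 with an estimated correlation). CXCL2 (-2.85 ± 0.22) and ICAM1 (-1.72 ± 0.16) were among them. Of 18 integrin subunits 5 were lower and 1 higher, or 5 and 2 over the list alone (median -0.16, 0.0288, or 0.25 estimated). Lower were ITGB7 (-1.16 ± 0.26), ITGB5, ITGA2 (-0.80 ± 0.19), ITGA6 (-0.65 ± 0.18) and ITGA5 (-0.63 ± 0.16), and higher was ITGA2B (1.86 ± 0.56), which was not called with reads of the series-wide table (1.43, adjusted p = 0.091) or without shRelA adherent replicate 1 (0.071), shRelB adherent replicate 2 (0.052) or shRelB spheroid replicate 4 (0.062). The integrin call ended without shRelA spheroid replicate 3 (adjusted p = 0.05) or shRelB spheroid replicate 1 (0.051).

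**Figure D3:**
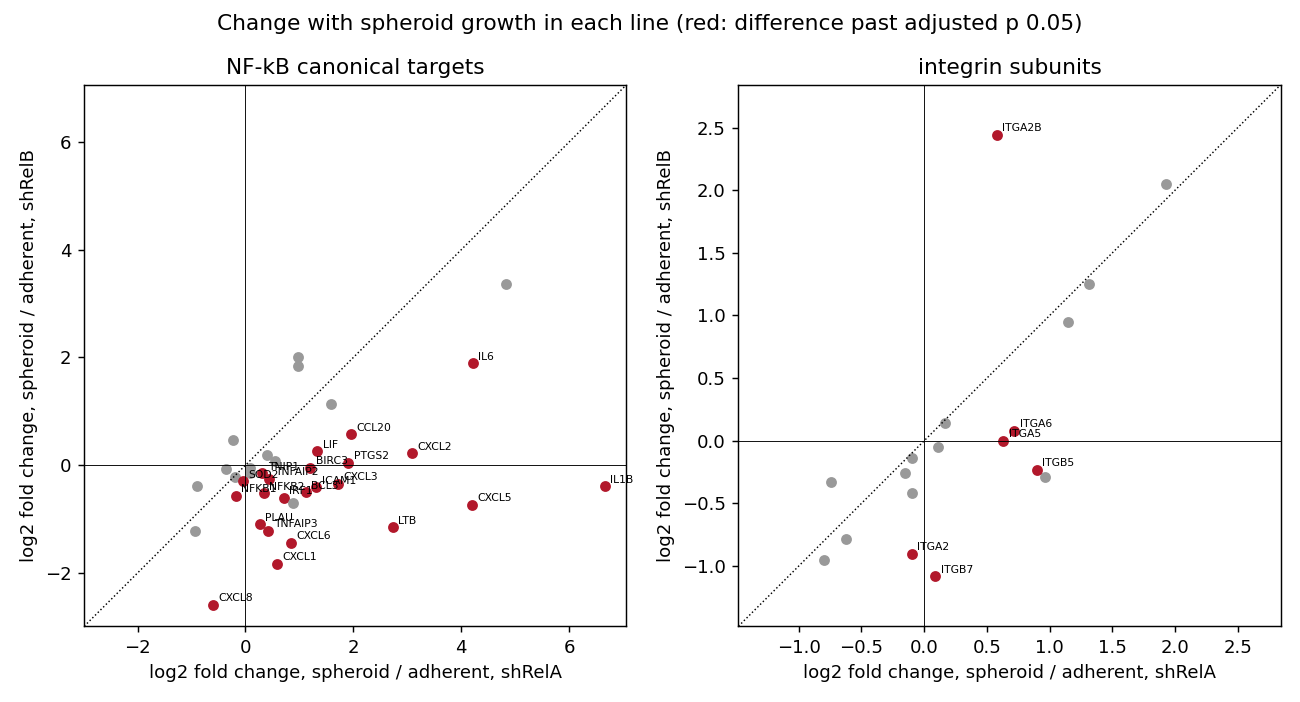
Each point is a gene, placed by its log2 change of spheroid over adherent growth in shRelA (x axis) and shRelB (y axis), for NF-kB canonical targets on the left and integrin subunits on the right; red points have a called difference between the lines and the dotted line marks equal change. The 23 NF-kB targets and 5 integrin subunits with a lower effect in shRelB lie below the dotted line.

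Ribosome biogenesis genes were lower in the difference in 19 of 29 and higher in 0, or 23 and 0 adjusted over the list alone (median -0.48, adjusted p = 6.2e-12, or adjusted p = 0.25 with an estimated correlation). NOP16 stood at -0.93 ± 0.14. NRF2 targets were lower in 10 of 23 and higher in 0, or 13 and 0 over the list alone (median -0.31, 0.000122, or 0.27 estimated). AKR1B10 stood at -1.72 ± 0.21. Glycolysis genes were lower in 9 of 18 and higher in 0, or 10 and 0 over the list alone (0.000818, or 0.3 estimated). HK1 stood at -0.55 ± 0.08. Immediate early genes were lower in 11 of 30 and higher in 1, or 12 and 1 over the list alone, DUSP5 at -0.95 ± 0.10 and DUSP6 at 0.78 ± 0.09 (0.000767, or 0.29 estimated). EMT genes were lower in 5 of 15 and higher in 1, the same over the list alone, with the collagen crosslinker LOX at -1.10 ± 0.10 (0.00212, or 0.24 estimated), and TGF-beta targets were lower in 8 of 21 and higher in 2, or 11 and 2 over the list alone, ID1 at -1.59 ± 0.16 (0.00385, or 0.13 estimated). Matrix genes were lower in 11 of 27 and higher in 3, or 11 and 4 over the list alone (0.0147, or 0.3 estimated). TNC stood at -2.22 ± 0.19. Beside them, 3 of 5 leukocyte markers were lower and 0 higher, or 3 and 1 over the list alone (median -0.74, camera adjusted p = 0.154). Of 5 endothelial markers 1 was lower and 0 higher, or 2 and 0 over the list alone (median -1.03, 0.141), and of 8 fibroblast markers 3 were higher and 4 lower, the same over the list alone (0.824).

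Cholesterol genes were higher in the difference in 10 of 25 and lower in 2, or 12 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.00154, or adjusted p = 0.52 with an estimated correlation). HMGCS1 stood at 1.05 ± 0.14. Mitosis genes were higher in 5 of 34 and lower in 0, or 11 and 0 over the list alone (0.00019, or 0.55 estimated), replication genes higher in 3 and lower in 0 of 34, or 2 and 0 over the list alone, PCNA at 0.46 ± 0.09 (0.00212, or 0.44 estimated), and recombination genes higher in 4 of 29 and lower in 0, the same over the list alone (0.0219, or 0.48 estimated). Epithelial genes were lower in 9 of 28 and higher in 1, or 13 and 3 over the list alone, with KRT8 at -0.85 ± 0.13 (0.0179, or 0.37 estimated), and focal adhesion genes lower in 8 of 26 and higher in 1, or 9 and 2 over the list alone, BCAR1 at -0.76 ± 0.11 (0.0219, or 0.48 estimated). Of 13 mitochondrially encoded genes MT-ND3 alone was called, lower by -0.50 ± 0.13, over all genes and over the list alone (median -0.60, 0.000193, or 0.48 estimated). Without shRelA adherent replicate 2 the matrix call ended (adjusted p = 0.055). Without genes of the chromosomal runs the EMT (0.1) and focal adhesion (0.07) calls ended, the last also without shRelA adherent replicate 1 (0.055) or replicate 3 (0.063).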

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

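The searches for neighbouring runs, the shuffled gene order, the GC and length correction, the label check, the counting interval of RELB, the check of RELB in the shRelA line, and the leave-one-out and run-free tests of the NF-kB list were tests chosen only after the result was seen.

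The spheroid effect differed between shRelB and shRelA by a direct test in 1108 genes with a higher and 1412 with a lower effect. Named genes with a higher effect in shRelB were TFEC (3.31), PDK4 (2.75), ADH1C (2.15), COL3A1 (2.11), LRRC31 (1.64) and TENT5C (1.61). Those with a lower effect were BPIFB1 (-4.50), TAAR1 (-3.89), LTB (-3.88) and IFI30 (-3.46), and CXCL5 and MYH4, whose fitted values (-4.93 and -4.57) depend on the prior count and are no bounds, because a group held 1 or 0 counts. TFEC was lost without shRelB spheroid replicate 3 (1.49, adjusted p = 0.71), shRelB adherent replicate 2 (adjusted p = 0.05) or shRelB adherent replicate 3 (0.052), and IFI30 with reads of the series-wide table (-0.55, adjusted p = 0.11). Lists that differed were NF-kB targets (adjusted p = 1.7e-14, median -1.25), ribosome biogenesis (6.2e-12, -0.48), NRF2 targets (0.00012, -0.31), mitosis (0.00019, 0.30), mitochondrially encoded genes (0.00019, -0.60), immediate early genes (0.00077, -0.26), glycolysis (0.00082, -0.31), cholesterol synthesis (0.0015, 0.29), replication (0.0021, 0.15), EMT (0.0021, -0.39), TGF-beta targets (0.0038, -0.34), matrix (0.015, -0.34), epithelial junctions (0.018, -0.34), focal adhesion (0.022, -0.22), homologous recombination (0.022, 0.11) and integrin subunits (0.029, -0.16). With an estimated correlation the NF-kB call alone was kept, and the other 15 were lost. Single libraries ended the integrin, matrix and focal adhesion calls, with adjusted p of 0.05 without shRelA spheroid replicate 3, 0.051 without shRelB spheroid replicate 1, 0.055 without shRelA adherent replicate 2, and for focal adhesion 0.055 and 0.063 without shRelA adherent replicate 1 or 3.

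In each of the 4 comparisons of groups, 1 of 35 splits of the samples called as many genes, the real one, the smallest share possible. For spheroid growth it called 7710 genes against 1 in the highest other split in shRelA, and 8142 against 0 in shRelB. For the lines it called 7319 against 0 in adherent cells and 6809 against 0 in spheroids. This argues against a chance division of these libraries. Chance differences between cultures are not excluded, because the replicates may not be separate cultures. For the difference between the lines, 3 of 100 splits gave as many genes, the real one included, with 2520 against 4213 in the highest other. These splits moved all 16 labels over the 4 groups, so differences of line and of growth could enter both the spread and the contrast. The share therefore cannot exclude chance for the difference between the lines. Why other splits gave more genes was not tested. For lists in shRelA spheroids, 1 of 35 splits was as large, the real one, with 19 lists against 18. Without shRelA adherent replicate 2 the real count was itself 18, so this margin is no wider than the effect of 1 library. That count does not measure chance, and no conclusion about chance is drawn from so narrow a margin. By this share, chance was not excluded for spheroid growth in shRelB (3 of 35, 19 against 19). Nor was it for the lines in adherent cells (11 of 35, 14 against 19) or spheroids (15 of 35, 4 against 7), or the difference (18 of 100, 16 against 18). Splits of 35 that exchanged only 1 library between groups kept part of the real difference. Evenly mixed splits called at most 13 lists in shRelA, 4 in shRelB, and 13 and 6 for the lines in adherent cells and spheroids. They put the real difference into the spread, so neither kind of split measures chance alone.

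In 8 of 198 groups tested a library lay far from the other 3, where chance gives about 10. They were AQP4 in shRelB adherent replicate 4 (4.75 CPM), PLXNC1 in shRelB spheroid replicate 2 (4.58), CXCL5 in shRelB adherent replicate 4 (36.6), TDO2 in shRelB adherent replicate 3 (2.83), RELB in shRelB adherent replicate 1 (7.32), NFKB1 in shRelB spheroid replicate 1 (35.3), NFKB2 in shRelA spheroid replicate 4 (25.3) and a gene not reported here in shRelB spheroid replicate 1 (30.0). The series-wide table also holds genes absent from the per-library tables, of which 624 of 15216 passed the filter, and 200 and 224 of these were called for spheroid growth in shRelA and shRelB, 190 and 171 for the lines in adherent cells and spheroids, and 49 for the difference.

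Runs of neighbouring genes differed between the lines in the same direction in both growth conditions, with 147 windows past the threshold in each. The real order had 111 windows past it in both conditions and 100 shuffles of the gene order had 0. The threshold was itself set from such shuffles, so their 0 was likely beforehand and is no separate test. The real count past that threshold argues against a chance order. After removal of the trend over GC content and transcript length, the median of the run genes kept 96% of its size in adherent cells and 96.8% in spheroids, so those trends are not the whole cause. A difference in copy number between the lines may explain the runs, since it should also move genes too low to find the runs with. These 228 genes had a median of 0.45 in the direction of their run in adherent cells and 0.48 in spheroids, where 95% of random runs stayed under 0.17 and 0.16. DNA was not measured, so this stays a hypothesis, and regulation over whole chromosome arms remains open.

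RELB was not lower in adherent libraries labelled shRelB. A single mislabelled library is argued against by RELA. Its level was at most 25.8 CPM in shRelA libraries and at least 47.2 in those labelled shRelB. In a score over the runs, too, 16 of 16 libraries lay on the side of their label. The runs were chosen by the labels, so the score is not independent of them. A wrong label carried by every library of a line could not show in the score. Counting error alone is argued against by the 505 and 580 RELB counts in adherent shRelA and shRelB libraries. Their ratio was 1.14 with a 95% counting interval of 1.01 to 1.28. A change of annotation is argued against by the reads of the series-wide table, which gave 0.19 on the log2 scale. RELB might also be lowered in the shRelA line, and the exact permutation p of 0.31 between the lines leaves that open, because no control shRNA is there to set both lines against. Adherent cells were kept in tetracycline-free serum, and the labels do not say whether the shRNA needs induction. In that serum RELA stood at 32.6% of the other line in shRelA cells, against 46% in spheroids. This bears on the shRNA against RelA alone. An shRNA against RelB that was not induced in adherent cells was not tested and stays open. It would change what each adherent comparison of the lines means. With spheroid growth RELB rose from 9.12 to 12.9 CPM in shRelA and fell from 10.5 to 7.44 in shRelB, and NFKB2 moved likewise. The lower RELB in spheroids labelled shRelB thus cannot be assigned to its shRNA alone.

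As a list, NF-kB targets were called higher in spheroids of shRelA, where 23 of 37 rose and 3 fell, and lower in those of shRelB, where 17 fell, 7 rose and 13 were not called. With an estimated correlation both calls were lost (adjusted p = 0.19 and 0.45) and the difference was kept (0.03). At the preset correlation the list stayed called in both lines and in the difference in 16 of 16 fits without 1 library. Its adjusted p ran from 4.1e-05 to 0.00054 in shRelA and from 0.013 to 0.04 in shRelB. This argues against a single library as the cause. With counts thinned to one depth the weaker call, in shRelB, had adjusted p = 0.028, and without genes of the runs it had 0.032, so depth and the runs are argued against as whole causes. A biological difference that the design names, the knockdown of RelA against that of RelB, stays open as a hypothesis, as do lasting differences between the lines unrelated to the shRNA.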

How the results depend on the processing

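Tests with reads of the series-wide table and without genes of the runs were chosen only after the result was seen. No result reversed. Of 16723 alternative values for 626 results of named genes, 16353 kept direction and side of the threshold, 367 fell short of it and 3 newly passed, and 263 of the 367 came from the 2-fold minimum, which asks for more than a difference from 0. That minimum left 1182 higher and 571 lower genes for spheroid growth in shRelA, 1169 and 637 in shRelB, 999 and 757 for the lines in adherent cells, 763 and 714 in spheroids, and 162 and 450 for the difference. With an estimated correlation 0, 0, 2, 0 and 1 lists stayed called in the 5 comparisons, against 19, 19, 14, 4 and 16, and without genes of the runs 7 lists were called for the lines in spheroids against 4; the cause was not tested. Leaving out each library gave 18 to 20, 18 to 20, 13 to 16, 4 to 5 and 15 to 21 lists, with 3670 to 4014, 3851 to 4273, 3316 to 3755, 3112 to 3580 and 882 to 1390 genes higher and 3456 to 3782, 3733 to 4109, 3423 to 3823, 3106 to 3604 and 1162 to 1591 lower. The mean log2 difference of RELA then ran from 1.54 to 1.63 in adherent cells and from 1.06 to 1.16 in spheroids, and that of RELB from 0.12 to 0.34 and from -0.84 to -0.66. In deposited TPM RELB differed by 0.38 in adherent cells (exact permutation p = 0.086, against 0.18 and 0.31) and by -0.68 in spheroids (0.029). With the replicate number as a block 3956 and 3700, 4115 and 3994, 3639 and 3653, 3346 and 3457, and 1122 and 1440 genes were called, and the paired exact sign-flip p was 0.125, the smallest possible, for RELA in both growth conditions and RELB in spheroids, and 0.25 for RELB in adherent cells. Of the calls of named genes 1 was lost with that block, for shRelB against shRelA in spheroids. Reads of the series-wide table called 8063, 8598, 7450, 6926 and 2528 genes. Lower depth was tested for the NF-kB list alone.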

Other observations

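The stretch on chromosome 22 was chosen only after the result was seen. The test of liver-secreted proteins was written after the largest changes were seen and before its own result.

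A stretch of chromosome 22 from 20394115 to 21002196, from ZNF74 to THAP7, held 11 expressed coding genes, of which 10 stood over 200 TPM, against 3.88% of all expressed coding genes. The median of the stretch was 564.6 TPM, and the 20 neighbours on either side had medians of 11.3 and 9.6. AIFM3, at 15.18 TPM, was the exception. SERPIND1 lies in this stretch and stood at 4690 ± 1040 CPM in adherent shRelA cells and 116 ± 25.2 in shRelB spheroids (SD, n = 4). These genes were chosen after their values were seen.

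APOB, SERPIND1 and FGA, which liver secretes, were among the largest falls in spheroids. The hypothesis that liver-secreted proteins fall more widely was tested on 25 other genes, of which 13 passed the filter. The test was negative. In shRelA 7 rose, with CP at 3.09, HP at 2.25 and AMBP at 2.01, and 3 fell, and camera gave 0.12 in the upward direction. In shRelB 4 rose and 4 fell, and camera gave 0.68. In the difference between the lines, which the hypothesis did not cover, 0 were higher and 6 lower. There camera gave 0.00059, or 0.09 with an estimated correlation. The camera p of this list were not adjusted, unlike those of the fixed lists. VTN is also in the list of integrin ligands and matrix.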
